A study of Homo sapiens with 120 samples.

How the data were processed

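H3K4me2, a histone mark of promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in CD4 T cells sorted from blood. The labels name naive cells and memory cells without and with the chemokine receptor CCR4, from 11 healthy and 12 asthmatic donors. The series has 120 libraries. A first and a second library of CCR4+ cells were at hand for 8 healthy and 12 asthmatic donors. For CCR4- cells these numbers were 5 and 11, and for naive cells 8 and 11. Healthy donors thus lacked a second library or a cell type more often than asthmatic ones. The growth protocol in the labels describes a cell line medium and does not match primary cells, so it was not used.

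Reads were aligned with Bowtie 0.12.7 to hg19 and handled with SAMtools and edgeR, per the submitters' processing notes. The deposited files are 2 tables of 500 bp windows, one for the cell type comparisons with 71640 windows and one for asthma against health with 200 windows. Per the file headers, the authors give an RPKM value and a normalized count for each library. The normalized count is a score that the authors normalized and rounded to whole numbers before the files were deposited. That it was quantile normalized is inferred from the letter q in the header of its mean columns and from its nearly equal distributions, and the labels do not say so. Its totals over the cell type windows run from 1228593 to 1539566 per library, against 740831 to 2169763 recovered reads. The authors also give log2 fold changes and, per the file headers, p-values and adjusted p-values for each comparison. Each window in the deposited tables has an adjusted p of the authors under 0.05 in at least 1 comparison. Both tables are thus selections, hold no unchanged background, and say nothing of how many windows of the genome changed. The tables share 20 windows.

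Every RPKM value of a library was a whole multiple of 1 step, within a tolerance of 0.02, for 100% of values. The step gave the mapped reads of each library, from 12.7 to 32.3 M (mega, reads) with a median of 22.3 M. A value of 1 RPKM stood for 11.2 reads per window in the median library, 6.35 in the shallowest and 16.2 in the deepest. Amplified reads carry no molecular identifiers, so this depth bounds counting error only.

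The design fixed before the data were examined called for a count test on raw counts, or for limma on RPKM where the tables hold none. Raw counts were not used here because the tables hold normalized ones, so limma 3.58.1 in R 4.3.3 was used. RPKM values were averaged over the libraries of a donor and cell type, and log2(RPKM + 1) was fitted with a mean-variance trend. Fold changes on that scale understate the change of windows with low signal, and plain ratios of mean RPKM are given beside them. The donor was the replicate. Windows were called at a Benjamini-Hochberg adjusted p under 0.05, over the 70441 autosomal windows of the cell type table or the 198 of the asthma table. One naive library with conflicting donor labels was left out of the fits. Chromosomes X and Y were left out of the main fits, and 12 empty columns of the cell type table were ignored. Asthma was also compared with health over the 70441 cell type windows, which were not selected on disease. The difference in the asthma effect between cell types was the interaction term of a fit over both cell types.

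Called windows of 1 direction that touch or lie within 1 window of each other were merged into regions. The regions named are, per comparison and direction, those among the 10 with the smallest adjusted p, each represented by its window with the smallest adjusted p. A gene annotation of hg19 was not used here, and the gene table at hand is of another build. Regions are therefore given by position, no gene is named and the gene lists fixed beforehand were not tested.

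On data simulated for the 70441 windows with 200 changed, the fit of CCR4+ against CCR4- memory cells recovered 94.0% of windows changed 2-fold and 49.3% of those changed 1.5-fold. For asthma in CCR4+ cells it recovered 74.6% at 2-fold and 23.9% at 1.5-fold, for CCR4- cells 62.7% and 19.4%, and for naive cells 64.2% and 19.4%. For the difference of the asthma effect between CCR4+ and CCR4- cells it recovered 81.8% at 3-fold, 43.3% at 2-fold and 5.97% at 1.5-fold. False calls in these simulations numbered 5 to 13. With only 200 changed windows, the simulations do not describe the cell type fits, where most windows were called. Nor do they describe fits over the asthma table, whose windows the authors had selected on disease. Of 100 splits of the real CCR4+ donors over these windows, 7 besides the real one gave asthma calls, at most 5988. The simulated false calls thus do not bound those of the real fits.

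Donor labels pair the cell types, which was checked on the values. Deviations from the group mean had a median correlation across windows of 0.13 between CCR4+ and CCR4- samples of 1 donor and -0.02 between samples of other donors. The values were 0.11 and -0.01 for CCR4+ and naive samples, and 0.09 and -0.01 for CCR4- and naive samples. The CCR4- sample most correlated with a CCR4+ sample was of its own donor in 8 of 19 pairs. It was so in 13 of 21 pairs of CCR4+ with naive samples and 5 of 18 of CCR4- with naive samples. The values thus go with the pairing as a whole but do not settle single pairs. The fit with the donor as a block was an alternative fixed beforehand, together with other thresholds, filters, scalings and choices of library. Libraries were checked for exchanged labels by their most correlated library. For 114 of 120 it was of the same cell type, and for 120 of 120 it was on the same side of naive against memory. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.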

Results

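H3K4me2 was mapped in naive, CCR4- memory and CCR4+ memory CD4 T cells of healthy and asthmatic donors. CCR4 is a chemokine receptor found on type 2 helper memory cells among others. CCR4+ memory cells were measured in 18 libraries of 10 healthy donors and 24 libraries of 12 asthmatic donors. CCR4- memory cells were measured in 13 libraries of 8 healthy and 23 libraries of 12 asthmatic donors. Naive cells were measured in 18 libraries of 9 healthy and 24 libraries of 12 asthmatic donors. Median depth per group lay between 21.9 and 23.2 M mapped reads (M, mega), and single libraries between 12.7 and 32.3 M. The share of a library's reads that fell in the 70441 autosomal cell type windows averaged 6.51% ± 0.85 (SD, n = 120). Positions below are 1-based in hg19, and every count refers to windows the authors had already selected.

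Naive libraries separated from those of both memory types, while CCR4- and CCR4+ libraries overlapped on the first and on the second principal component. The first principal component of log2(RPKM + 1) held 31.9% of the variance, and cell type accounted for 94.4% of its scores. The second component held 11.0%. Taken singly, the share of reads in the windows accounted for 83.8% of its scores and cell type for 46.6%. The fourth component held 2.28%, of which the library number, first or second from a donor, accounted for 40.2% and disease for 12.4%.

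**Figure D1:**
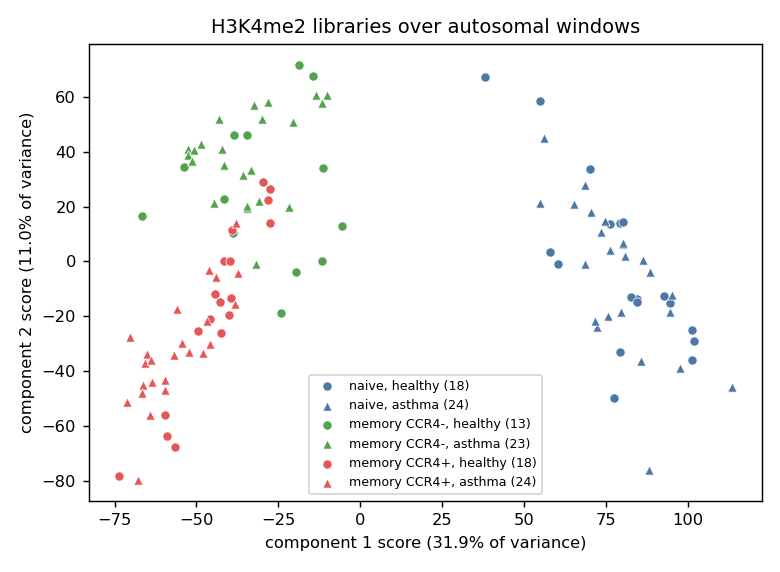
Scores of the 120 libraries on the first 2 principal components of log2(RPKM + 1) over 70441 autosomal windows. Colours mark the cell type and shapes the donor group; naive libraries lie apart from both memory types along component 1, which holds 31.9% of the variance.

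CCR4+ memory cells were compared with naive cells to find regions whose mark changes with memory formation. The window with the smallest adjusted p among the gains lay on chromosome 11 at 117152001 to 117152500, in a region of 15500 bp. It averaged 8.42 RPKM ± 1.78 (SD, n = 22) in CCR4+ donors and 1.21 ± 0.37 (SD, n = 21) in naive donors, a ratio of 6.98. The next was a region of 39500 bp on chromosome 5 from 156962001 to 157001500, whose leading window rose from 1.14 ± 0.31 (SD, n = 21) to 6.68 ± 1.26 RPKM (SD, n = 22). A region of 6500 bp on chromosome 1 from 159042501 to 159049000 rose 7.25-fold, and one of 10500 bp on chromosome 8 from 27933001 to 27943500 rose 5.78-fold. A window on chromosome 11 at 9599001 to 9599500 had the highest level among the 10 named gains, at 19.5 ± 3.68 RPKM in CCR4+ cells (SD, n = 22) and 4.73 ± 1.56 in naive cells (SD, n = 21). Among the losses, the region on chromosome 13 from 100061501 to 100071500 led, with 3.22 ± 0.73 RPKM in CCR4+ cells (SD, n = 22) against 16.7 ± 3.40 in naive cells (SD, n = 21). A region of 7000 bp on chromosome 6 from 90997001 to 91004000 fell 5.16-fold, and one of 13000 bp on chromosome 18 from 5156501 to 5169500 fell 5.04-fold. On chromosome 4, a region from 22668001 to 22679500 fell 4.59-fold. All 21 donors with both cell types moved in the direction of the call at each of the 20 named regions. The regions were chosen for the smallest adjusted p in these same donors, which favours such agreement.

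In the limma fit, 32553 windows were higher and 32009 lower in CCR4+ than in naive cells, of 70441 tested. They merged into 12461 and 13487 regions. The median RPKM ratio was 0.94 on the log2 scale among gains and -0.84 among losses, and 14492 gains and 10329 losses reached a 2-fold ratio. The leading gain on chromosome 11 changed by 2.09 ± 0.08 (SE) on the log2(RPKM + 1) scale with a limma adjusted p of 1.56e-41, and the leading loss by -2.06 ± 0.08 with 5.27e-40. The longest merged loss spanned 59000 bp on chromosome 15 from 99194501 to 99253500 and held 116 windows. The longest merged gain spanned 45000 bp on chromosome 10 from 33370001 to 33415000 and held 86 windows.

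CCR4- memory cells were compared with naive cells in the same way. The leading gain was a region of 17500 bp on chromosome 14 from 65172001 to 65189500, where the leading window averaged 7.02 ± 2.34 RPKM (SD, n = 20) in CCR4- and 1.65 ± 0.62 (SD, n = 21) in naive donors. CCR4+ donors averaged 6.85 RPKM in that window. A window on chromosome 9 at 124117001 to 124117500 averaged 2.23 ± 0.49 RPKM (SD, n = 20) in CCR4- cells, 0.42 ± 0.21 (SD, n = 21) in naive cells and 1.24 in CCR4+ cells. The region on chromosome 5 from 156962501 to 157001500 was among the named gains here too, at 4.18 ± 1.02 RPKM (SD, n = 20). The leading loss was again the region on chromosome 13 from 100061501 to 100071500, at 3.73 ± 1.23 RPKM (SD, n = 20). A region on chromosome 5 from 148674001 to 148681500 fell 4.18-fold to 2.67 ± 0.61 RPKM (SD, n = 20), and one of 32000 bp on chromosome 3 from 60035501 to 60067500 fell 4.92-fold. At the last, CCR4+ cells averaged 2.03 RPKM against 0.87 in CCR4- and 4.28 in naive cells. All 18 donors with both cell types moved in the direction of the call at each of the 20 named regions, which were likewise chosen in these donors.

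The limma fit called 28806 windows higher and 34191 lower in CCR4- than in naive cells. The excess of losses depends on the scaling, with 32086 higher and 32889 lower after centring and 30330 and 30133 with the share of reads as a covariate. The leading gain changed by 1.57 ± 0.10 (SE) on the log2(RPKM + 1) scale with a limma adjusted p of 9.11e-26, and the leading loss by -1.92 ± 0.09 with 5.49e-32. The median window moved by -0.08 on that scale, and the share of reads in the windows was 5.87% ± 0.56 in CCR4- samples (SD, n = 20) against 6.75% ± 0.66 in naive ones (SD, n = 21).

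The memory subsets changed many windows alike against naive cells. Both were higher in 25287 windows and both lower in 30602, where independent lists of the same lengths would share 13312 and 15537. The authors had selected these windows for a call in the cell type comparisons, so the excess over independent lists is not a test. With the naive donors divided between the comparisons, 21717 and 29458 windows were shared, or 22897 and 28564 with the parts exchanged. The changes correlated across windows with a Pearson r of 0.86 and a covariance of 0.19. For simulated unchanged groups that shared simulated naive samples the values were 0.50 and 0.003. That simulation had independent noise and no selection of windows, so it shows only what a shared control adds under such noise. Windows are not independent replicates. In windows called higher in CCR4+ than naive cells in one part of the donors, the CCR4- mean of the other donors lay between naive and CCR4+ cells for 76.8% and 74.2% of windows, depending on the part. Among losses it lay between them for 55.8% and 50.3%, and past the CCR4+ mean for 42.8% and 48.0%. With calls from the first part, the median change of gains in the other donors was 0.46 in CCR4+ and 0.30 in CCR4- cells, and of losses -0.45 and -0.44, on the log2(RPKM + 1) scale. With calls from the second part it was 0.48 and 0.29 for gains, and -0.46 and -0.47 for losses. This contrast between gains and losses depends on the scaling. With each sample centred on its median window, the CCR4- mean lay between the others for 70.2% and 67.3% of gains and for 69.4% and 68.3% of losses.

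**Figure D2:**
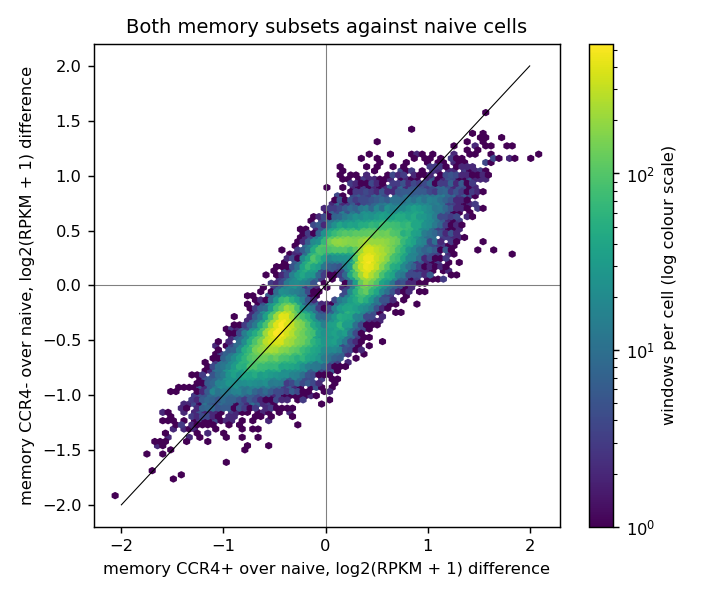
Change against naive cells in CCR4+ memory cells (x axis) and CCR4- memory cells (y axis), as differences of mean log2(RPKM + 1), for 70441 windows; colour gives the number of windows per hexagon on a log scale and the black line marks equal change. Pearson r across windows was 0.86, and the naive samples are shared by both axes.

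CCR4+ memory cells were compared with CCR4- memory cells to find regions that mark the CCR4+ subset. Of the 10 named gains, 4 lay on chromosome 3 between 32989001 and 33106500. The leading window there, at 32995001 to 32995500, averaged 9.41 ± 2.26 RPKM (SD, n = 22) in CCR4+, 2.60 ± 0.70 (SD, n = 20) in CCR4- and 1.91 ± 0.62 (SD, n = 21) in naive donors. In the 100000 bp from 33000001, 132 of the 134 windows in the table were higher in CCR4+ cells and 0 were lower. Other named gains were a window on chromosome 17 at 49513501 to 49514000 that was 2.74-fold higher, one on chromosome 2 at 12003001 to 12003500 that was 2.38-fold higher, and one on chromosome 10 at 9059001 to 9059500 that was 3.63-fold higher. In each of those 3, CCR4- and naive means were close, at 1.84 and 1.74, 3.02 and 3.15, and 0.72 and 0.90 RPKM. A window on chromosome 21 at 32519501 to 32520000 had another order, with 12.6 RPKM in CCR4+, 5.84 in CCR4- and 15.8 in naive cells.

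Windows lower in CCR4+ than CCR4- cells were led by regions on chromosome 5 from 148229501 to 148241500 and on chromosome 17 from 34215501 to 34230500. The leading window on chromosome 5 averaged 1.80 ± 0.58 RPKM (SD, n = 22) in CCR4+, 4.23 ± 1.39 (SD, n = 20) in CCR4- and 1.57 ± 0.72 (SD, n = 21) in naive donors. The leading window on chromosome 17 averaged 1.75 ± 0.56 (SD, n = 22), 4.48 ± 1.75 (SD, n = 20) and 1.51 ± 0.54 RPKM (SD, n = 21) in the same order. A window on chromosome 8 at 128684501 to 128685000 was 2.40-fold lower in CCR4+ cells, one on chromosome 10 at 72378501 to 72379000 was 2.88-fold lower, and one on chromosome 16 at 85133501 to 85134000 was 2.15-fold lower. All 19 donors with both memory types moved in the direction of the call at 16 of the 20 named regions, and 18 of 19 did at the other 4. These regions too were chosen in the same donors. On chromosome 15, 148 of the 189 windows in the table from 99200001 to 99300000 were lower in CCR4+ than CCR4- cells, and all 189 were lower in CCR4+ than in naive cells.

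**Figure D3:**
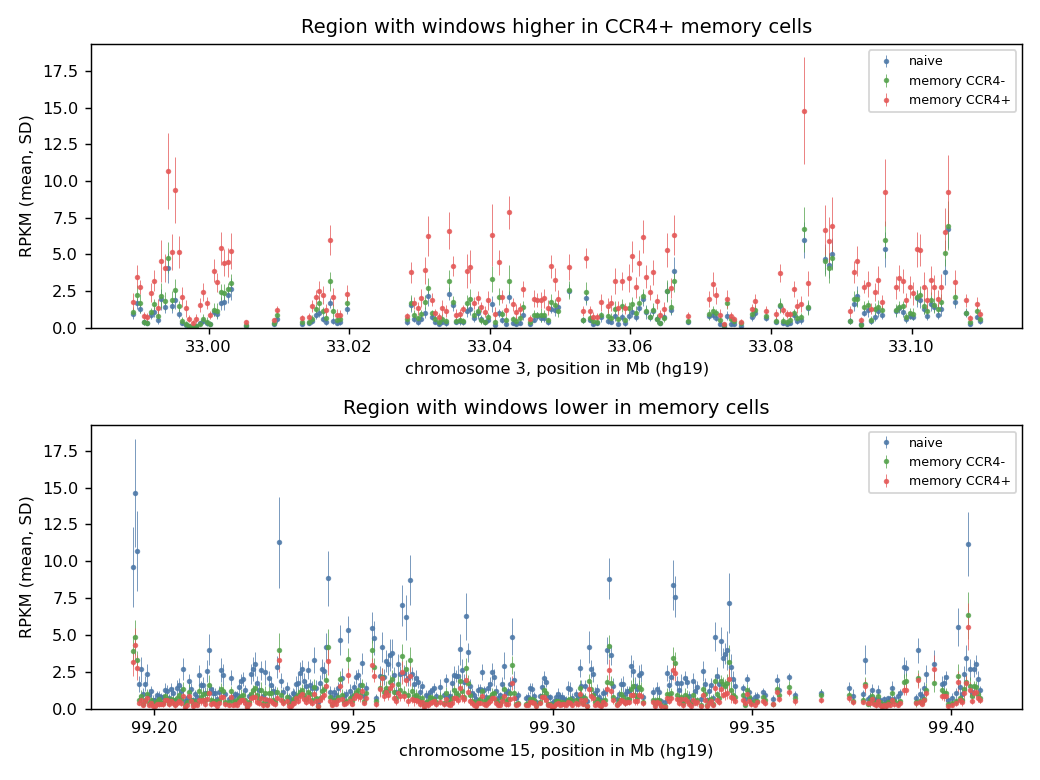
RPKM per 500 bp window, mean and SD over donors, in naive (n = 21), CCR4- (n = 20) and CCR4+ (n = 22) cells along 2 regions, with positions in Mb of hg19. Only windows of the cell type table are drawn, so gaps are not zeros; the leading window on chromosome 3 averaged 9.41 RPKM in CCR4+ and 2.60 in CCR4- cells.

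The limma fit called 27002 windows higher and 10682 lower in CCR4+ than in CCR4- cells, with a median ratio among them of 0.55 and -0.50 on the log2 scale. The leading gain changed by 1.53 ± 0.09 (SE) on the log2(RPKM + 1) scale with a limma adjusted p of 1.06e-25, and the leading loss by -0.88 ± 0.09 with 5.80e-13. CCR4+ samples had 6.71% ± 0.66 of their reads in the windows (SD, n = 22) against 5.87% ± 0.56 (SD, n = 20) in CCR4- samples, higher in 19 of 19 donors by 1.00 point on average (permutation p = 3e-05, two-sided). Centring each library on its median window gave 18667 higher and 19066 lower, and the share as a covariate gave 13496 and 13573, so the excess of gains depends on the scaling. The named regions kept their calls under both.

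The window-wise values of the authors were set against the donor-level fit. The authors called 51261 windows for CCR4+ against naive, 38665 for CCR4- against naive and 9737 for CCR4+ against CCR4- cells, on all chromosomes. Of their autosomal calls, 50433 of 50437, 37958 of 38151 and 9365 of 9561 passed the limma fit in the same direction. Their log2 fold changes correlated across windows with the log2(RPKM + 1) differences with Pearson r of 0.94, 0.93 and 0.88. For asthma they called 163 windows in CCR4+, 11 in CCR4- and 29 in naive cells. Of the autosomal ones, 158 of 162, 6 of 11 and 28 of 28 passed the limma fit in the same direction, with r of 0.82, 0.82 and 0.78. Against the plain log2 ratio of mean RPKM, r was 1.00, 0.99 and 0.97 for the cell types in the order above, and 0.99 in each asthma comparison, so the lower r values come with the log2(RPKM + 1) scale. Of the 5 calls in CCR4- cells that did not pass, 4 had over 50% of the summed donor signal in 1 donor. The limma fit used the same libraries and was adjusted only over windows the authors had selected, which favours such agreement. For cell types in the order above it called 64562, 62997 and 37684 windows, and 64712, 63256 and 41342 had an unadjusted p under 0.05. For asthma in CCR4+, CCR4- and naive cells it called 179, 7 and 97, and 179, 19 and 113 did. The agreement is therefore not an independent check, and call counts of the fit and the authors do not compare directly.

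Asthmatic and healthy donors were compared within each cell type to find regions linked to the disease. The 198 windows were selected by the authors for this difference in the same libraries, so their calls are not independent evidence. In CCR4+ cells, the window on chromosome 1 at 243932501 to 243933000 averaged 0.77 ± 0.23 RPKM in asthmatic donors (SD, n = 12) and 2.08 ± 0.53 in healthy donors (SD, n = 10). A window on chromosome 7 at 51701501 to 51702000 averaged 0.51 ± 0.16 (SD, n = 12) and 1.41 ± 0.34 RPKM (SD, n = 10). Windows on chromosome 11 at 21919001, on chromosome 10 at 5423501 and on chromosome 7 at 109822501 were 3.00-fold, 2.85-fold and 3.18-fold lower in asthma. The last had low signal, at 0.28 ± 0.14 RPKM in asthmatic (SD, n = 12) and 0.90 ± 0.24 in healthy donors (SD, n = 10). In the other direction, a window on chromosome 6 at 33846501 to 33847000 averaged 1.16 ± 0.25 RPKM in asthmatic (SD, n = 12) and 0.47 ± 0.18 in healthy donors (SD, n = 10). A window on chromosome 21 at 30395001 was 1.81-fold higher in asthma, and 1 on chromosome 5 at 118614501 was 1.62-fold higher, with 8.70 RPKM in asthmatic and 5.38 in healthy donors.

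The limma fit called 144 windows lower and 35 higher in asthmatic CCR4+ cells, 7 lower and 0 higher in CCR4- cells, and 90 lower and 7 higher in naive cells. The window on chromosome 1 changed by -0.79 ± 0.09 (SE) on the log2(RPKM + 1) scale with a limma adjusted p of 2.98e-07, and the one on chromosome 6 by 0.55 ± 0.08 with 3.08e-06. Of the 144 windows lower in CCR4+ cells, 84 were also called lower in asthmatic naive cells, where the median change of the 144 was -0.31. The authors' own calls in CCR4+ and naive cells shared only 2 windows. The limma fit was adjusted only over windows the authors had selected, and both cell types came largely from the same donors. The 84 windows are thus not independent evidence of a difference shared by the cell types. Of the 35 windows higher in CCR4+ cells, 24 had the same direction in naive cells and 5 were called, with a median change of 0.10. In naive cells these 35 differed by 0.29 between asthmatic and healthy donors within the first libraries and by -0.02 within the second ones. The 144 windows differed there by -0.35 within the first and by -0.35 within the second libraries. In CCR4- cells the same 144 windows had a median change of 0.04, and 4 were called lower. The window on chromosome 1 averaged 0.98 ± 0.31 RPKM in asthmatic (SD, n = 12) and 1.98 ± 0.26 in healthy naive samples (SD, n = 9), and 0.96 and 1.07 RPKM in CCR4- samples. In naive cells the call with the smallest adjusted p was a window on chromosome 13 at 108303501 to 108304000, with 0.10 ± 0.09 RPKM in asthmatic (SD, n = 12) and 0.71 ± 0.28 in healthy donors (SD, n = 9), and a limma adjusted p of 2.05e-06. In CCR4- cells it was a window on chromosome 7 at 1562501 to 1563000, with 0.34 ± 0.13 (SD, n = 12) and 0.99 ± 0.37 RPKM (SD, n = 8), and a limma adjusted p of 0.000596. The call in CCR4- cells on chromosome 6 at 32551001 to 32551500 rested on uneven healthy donors, at 0.77 ± 0.94 RPKM (SD, n = 8).

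The windows lower in asthma also differed between the first and second libraries of the same donor, and those higher in asthma did so in part of the groups. Averaged over the 144 windows lower in asthma, the first library exceeded the second by 0.41 ± 0.07 on the log2(RPKM + 1) scale (SD) in 8 of 8 healthy CCR4+ donors (exact sign-flip p = 0.00781, adjusted over 12 tests 0.0117). It exceeded it by 0.17 ± 0.07 (SD) in 12 of 12 asthmatic CCR4+ donors (exact p = 0.000488, adjusted 0.00293). In naive cells the first library was higher in 8 of 8 healthy donors by 0.28 and in 11 of 11 asthmatic donors by 0.24 (exact p = 0.00781 and 0.000977, adjusted 0.0117 and 0.00391). Each of these exact p values is the smallest that its number of donors can give. In CCR4- cells, where these windows had a median asthma change of 0.04, the first library was higher in 5 of 5 healthy donors by 0.24 (exact p = 0.0625, the smallest 5 donors can give, adjusted 0.0833). It was higher in 10 of 11 asthmatic donors by 0.12 (exact p = 0.00195, adjusted 0.00585). Over the 35 windows higher in asthma, the first library was lower in 8 of 8 healthy and 12 of 12 asthmatic CCR4+ donors, with differences of -0.33 and -0.14 (exact p = 0.00781 and 0.000488, the smallest possible, adjusted 0.0117 and 0.00293). It was lower in 8 of 8 healthy naive donors, with a difference of -0.35 (exact p = 0.00781, the smallest possible, adjusted 0.0117). The difference did not pass the test in asthmatic naive donors (-0.01, first higher in 4 of 11, exact p = 0.846) or in healthy and asthmatic CCR4- donors (0.09 and -0.03, first higher in 4 of 5 and 5 of 11, exact p = 0.312 and 0.369). Asthmatic minus healthy CCR4+ libraries differed by -0.59 within the first and -0.43 within the second libraries over the 144 windows, and by 0.58 and 0.41 over the 35. These windows were chosen for that difference in the same libraries, so it is not tested again here.

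**Figure D4:**
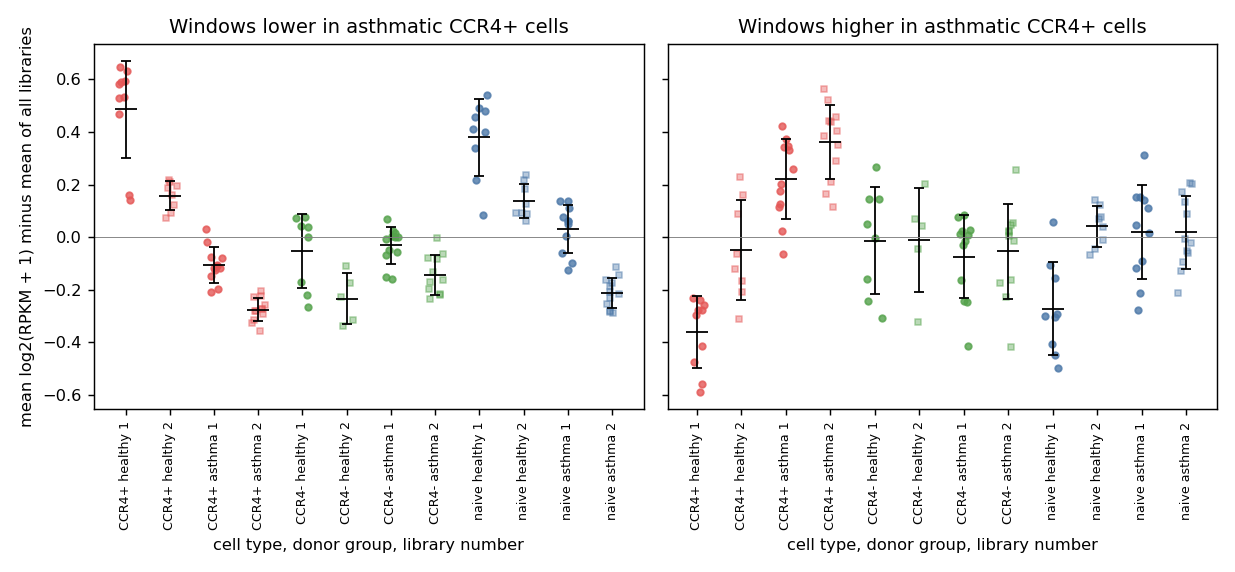
Mean log2(RPKM + 1) over the 144 windows lower (left) and the 35 windows higher (right) in asthmatic CCR4+ cells, minus the mean of all libraries; points are libraries, bars are mean and SD, and the number on the x axis is the library number of the donor. Healthy CCR4+ first libraries average 0.49 and second libraries 0.16 in the left panel, and asthmatic ones -0.11 and -0.28.

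Over the 70441 cell type windows, which were not selected on disease, the limma fit called 313 windows higher and 82 lower in asthmatic CCR4+ cells, and 2 higher and 16 lower in asthmatic naive cells. The direction in CCR4+ cells depends on the scaling, with 161 higher and 219 lower after centring each library on its median window and 56 and 155 with the share of reads as a covariate, both of which level the windows by construction. In CCR4- cells it called 0, with 2826 windows at an unadjusted p under 0.05, and limma-voom on the recovered reads called 0 with 3122. Both of these unadjusted counts are below the 0.05 share of the 70441 windows that unchanged windows would give on average. The first libraries alone gave 5206 higher and 415 lower in CCR4+ cells, and the second libraries alone 42 and 333. In naive cells the first libraries gave 1260 higher and 112 lower, and the second libraries 389 and 4815. The share of reads in the windows is made of the same windows, so it is no independent check on these directions. It turned from higher to lower in asthmatic naive cells, while in second libraries of CCR4+ cells the groups did not differ clearly. In first libraries of CCR4+ cells it was 6.93% ± 0.62 in asthmatic (SD, n = 12) and 5.95% ± 0.49 in healthy donors (SD, n = 10). In second libraries it was 6.98% ± 0.57 (SD, n = 12) and 7.14% ± 0.82 (SD, n = 8). The permutation p was 0.00088 and 0.599, adjusted over 6 tests 0.00264 and 0.599. In naive cells it was 7.18% ± 0.92 (SD, n = 11) and 6.12% ± 0.75 (SD, n = 9) in first libraries, and 6.39% ± 0.61 (SD, n = 12) and 7.44% ± 0.48 (SD, n = 8) in second ones (permutation p = 0.0118 and 8e-04, adjusted 0.0236 and 0.00264). The direction of most disease calls over these windows was thus set by which libraries were used.

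The difference in the asthma effect between cell types was tested as an interaction. Over the 198 windows of the asthma table, the effect in CCR4+ cells was above that in CCR4- cells in 37 windows and below it in 128. The effect in naive cells was above that in CCR4- cells in 8 windows and below it in 63. These windows were selected for an effect in 1 of the cell types, which favours such differences. Over the 70441 cell type windows the limma fit called 0 for either difference, with 6991 and 4525 windows at an unadjusted p under 0.05. With the donor as a block it called 25 windows, 12 above and 13 below, for CCR4+ against CCR4- cells and 0 for naive against CCR4- cells. Limma-voom on the recovered reads called 0 for either, with 7598 and 4691 windows at an unadjusted p under 0.05. The unadjusted counts of both fits are above the 0.05 share that unchanged windows would give on average, but windows are not independent. The counts of called windows depend on the libraries used. For CCR4+ against CCR4- cells the first libraries alone gave 1145 above and 45 below, and the second libraries 2 and 8. For naive against CCR4- cells the first libraries gave 573 above and 28 below, and the second libraries 57 and 629, the opposite direction.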

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

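The tests in this part were chosen after the results they concern were seen, except the interaction fits and the search for single distant donors. Of 47 groups of 8 to 10 healthy donors searched, 4 held 1 donor far from the others, and chance alone flags about 1 in 20 groups. They were healthy CCR4+ donors at chromosome 5 position 118614501 (gap over range 0.51), chromosome 11 position 134143501 (0.49) and chromosome 14 position 80327001 (0.53), and healthy naive donors at chromosome 8 position 93049001 (0.60). Without that donor the limma adjusted p was 3.93e-06, 1.17e-05, 8.02e-06 and 5.20e-05. The asthma effect differed between CCR4+ and CCR4- cells in 165 of the 198 asthma windows, and between naive and CCR4- cells in 71, by the interaction term.

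The first pattern is the set of 144 windows lower and 35 higher in asthmatic CCR4+ cells. The library number as the whole cause is argued against. The share of first libraries averaged 0.60 per healthy and 0.50 per asthmatic CCR4+ donor. With the highest first minus second difference, these shares give -0.041 on the log2 scale against the median of -0.51. An unlabelled library batch that differs between the healthy and the asthmatic libraries is a candidate explanation. The 144 windows had a median first minus second difference of 0.26 within CCR4+ donors, where 1000 random sets of cell type windows gave -0.10 to -0.02. In CCR4- donors, where their median asthma change was 0.04, it was 0.13 against -0.02 to 0.08. Of single cell type windows, 1.25% were at least as high in CCR4+ donors and 25.2% in CCR4- donors. The 35 windows had -0.22 against -0.15 to 0.02 in CCR4+ donors, where 12.25% of single windows were as low. In naive donors they had -0.15 against -0.10 to 0.06. In CCR4- donors they had 0.01, inside the random range of -0.07 to 0.12. The random sets were not matched on signal or spread, and the asthma windows were chosen for a difference among the same libraries. Such a choice favours windows that vary between libraries, so the random sets do not decide for a batch. Healthy CCR4+ first libraries averaged 0.57 over the 144 windows in the 8 donors with a second library and 0.15 in the 2 without. Over the same windows, 1 healthy naive donor had 0.34, 0.22 and -0.21 in libraries 1, 2 and 3. A difference between asthmatic and healthy donors stays open, with a median of -0.31 for the 144 windows in naive cells and 0.10 for the 35, of which 24 had the same direction and 5 were called, but no label gives the batch of a library, so it cannot be told apart from such a batch.

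The second pattern is the excess of higher over lower windows in asthmatic CCR4+ cells over the cell type windows. A gain of H3K4me2 over most windows in asthma did not show in both library numbers. Only 11.2% of calls from the second libraries were higher in asthma, against 88.7% of those from the first libraries of the same 20 donors. Such a gain is not excluded, since libraries that differ in the share of reads in the windows could hide it or mimic it. Libraries that differ in the share of reads in the windows stay open, as that share is made of the same windows and so the 11.2% cannot decide it. Centring and the share as a covariate level the windows by construction and decide nothing here.

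The last pattern is the excess of windows higher in CCR4+ than in CCR4- cells, 71.7% of calls. With the share of reads in the windows as a covariate 49.9% were higher. That share is made of the same windows, so this cannot be told apart from a general difference between the cell types.

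Other splits of the donors were drawn, 100 per result with the real one included. Where the windows had been selected by the authors on the real groups, the splits decide nothing. In each of these only 1 split, the real one, gave as many calls. The real and highest other counts were 37684 and 21914 for CCR4+ against CCR4-, 64562 and 39937 for CCR4+ against naive, and 62997 and 35948 for CCR4- against naive, with labels exchanged within donors. For asthma they were 179 and 120 in CCR4+, 7 and 1 in CCR4- and 97 and 26 in naive cells, and for the interactions 165 and 2, and 71 and 20. Over the cell type windows, 2 of 100 splits, the real one included, gave as many calls as the real 395 in CCR4+ cells. The other of these splits gave 5988, more than the real one, and what its groups share was not tested. Few random splits thus gave as many calls, but 1 gave more, so the count alone does not point to asthma. In naive cells 1 of 100 splits, the real one, gave 18 or more, with 5 as the highest other. That count rose or fell with other settings, as given below, so the splits bear on the main setting only. In CCR4- cells and in both interactions over these windows the real count was 0, so all 100 splits gave as many by construction and decide nothing about chance; the highest other counts were 82, 0 and 1.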

How the results depend on the processing

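The second libraries alone, the first libraries of donors with a second one, the authors' normalized counts, limma-voom, centring, the covariate, the fit without a trend, single libraries as replicates and the conflicting library by its column name were added after the data were seen. Named regions never reversed in the fits that held them. In 20 fits named asthma windows missed the threshold, 11 of them with the second libraries alone. The fit of windows above the median RPKM held only 7 of 20 named asthma windows in CCR4+ cells. It held 1 of 7 in CCR4- and 4 of 17 in naive cells, so most have low signal and were not tested there. DESeq2 and filterByExpr were not run because the tables as used here hold RPKM and normalized counts; limma-voom on reads recovered from the RPKM steps was run in their place, and the gene list alternatives were not run for lack of an hg19 annotation used here. The replicate block (donor) gave 40435, 64967 and 62184 windows for CCR4+ against CCR4-, CCR4+ against naive and CCR4- against naive cells, and 172, 65, 25 and 0 for the interactions; except for the 25 it moved no count by over 1.5 times. Causes were not tested unless stated.

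A minimum fold of 2 on the log2(RPKM + 1) scale left 24 windows (24 higher) for CCR4+ against CCR4-, 1417 for CCR4+ against naive and 599 for CCR4- against naive, 2, 0 and 1 for asthma in CCR4+, CCR4- and naive cells, 1 and 0 for asthma in CCR4+ and naive cells over the cell type windows, and 7 and 6 for the interactions of the asthma table. That scale shrinks folds of low windows by construction. On the plain RPKM ratio, 1597 called windows higher and 461 lower for CCR4+ against CCR4- reached 2-fold, 14492 and 10329 for CCR4+ against naive, 7930 and 10325 for CCR4- against naive, 8 and 72 for asthma in CCR4+, 5 lower in CCR4-, and 2 and 31 in naive cells. Merging gave 20743, 25948 and 27516 regions for the cell types. Windows above the median RPKM, which are fewer by construction, gave 21609, 31391 and 30701 for the cell types, 94, 1 and 51 for asthma, and 85 and 34 for the interactions. Healthy donors alone, with 18 samples, gave 14224 for CCR4+ against CCR4- cells. An adjusted p of 0.01 gave 63 for asthma in naive cells and 38 for the naive interaction.

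For asthma in CCR4+ cells over the cell type windows, an adjusted p of 0.01 gave 40 and of 0.1 gave 1465, first libraries 5621 (5206 higher, 415 lower), those of donors with a second one 5893 (5225 and 668), second libraries 375 (42 and 333), normalized counts 707 (421 and 286), limma-voom 151 (97 and 54), centring 380 (161 and 219), the covariate 211 (56 and 155) and libraries as replicates 1201. For naive cells there, an adjusted p of 0.01 gave 2, a pseudocount of 0.1 gave 7, first libraries 1372, those of donors with a second one 2589, second libraries 5204, limma-voom 9, the covariate 30 and no trend 1. The interaction of CCR4+ against CCR4- cells gave 100 with the second libraries in the asthma table. Over the cell type windows it gave 7 at an adjusted p of 0.1, 1190 with first libraries, 10 with second libraries, 25 with the block, 11 with centring, 6 with the covariate and 34 with libraries as replicates. The naive interaction there gave 601 with first libraries, 686 with second libraries, 1 with normalized counts and 2 with the covariate. For CCR4+ against CCR4- cells, centring turned 71.7% higher into 49.5%. The median window was at 0.09 on the log2(RPKM + 1) scale, and at 0.18 with limma-voom and 0.13 with the authors' normalized counts, whose log scales shrink low windows less.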

Other observations

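The bin counts and the test in this part were chosen after the data were seen. The 100000 bp with the most windows lower in CCR4+ than in naive cells lay on chromosome 15 from 99200001, with 189 of 189 windows in the table, and on chromosome 6 from 90800001, with 151 of 154, and from 90900001, with 141 of 141. CCR4- cells were lower than naive cells in 189, 150 and 140 windows of the same bins. The bins with the most gains in CCR4+ cells lay on chromosome 3 from 33000001 (134 of 134), chromosome 20 from 47300001 (122 of 125), chromosome 10 from 33300001 (117 of 117) and chromosome 5 from 156900001 (112 of 112). On chromosome 20 CCR4- cells also gained 122 of 125 windows, with a median log2 RPKM ratio of 1.01 against 0.94 in CCR4+ cells. On chromosome 4 from 109000001, 116 of 134 windows were higher in CCR4+ than in CCR4- cells, and 130 of 134 were lower in CCR4- than in naive cells.

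Over the 3 comparisons, the most common set of calls was lower in both memory types than in naive cells with no call between them, in 21057 windows or 29.9%. Another 11703 windows, 16.6%, were higher in both memory types and higher in CCR4+ than CCR4- cells. About as many, 11383 or 16.2%, were higher in both memory types with no call between them. In 6061 windows CCR4+ cells were higher than both other types with no call between CCR4- and naive cells. Calls between the memory types depend on the scaling, so the sets that rest on them may shift with it. Only CCR4- cells were raised in 3082 windows, higher than naive and CCR4+ cells with no call between those. In 1136 windows CCR4+ cells were above and CCR4- cells below naive cells, and in 315 the order was the opposite.

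Windows of a bin may change in the same direction when a stretch of chromatin is marked as a whole. In the 825 bins of 100000 bp with 10 or more calls between CCR4+ and CCR4- cells, 95.5% of the 15706 calls had the direction of their bin, against at most 77.9% in 1000 shuffles of the directions. In 551 bins all calls had 1 direction, against at most 41 in a shuffle. Fragments that span neighbouring windows and merged peaks would add to this and were not separated from it.

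Of the 198 asthma windows, 20 were also in the cell type table and 55 lay within 5000 bp of a window of it. Repeat libraries of a donor and cell type correlated across the cell type windows with a median r of 0.85, and other libraries of the cell type with 0.83.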
